A study of Papio sp. with 35 samples.

How the data were processed

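Total RNA from left ventricle of 35 female baboons was sequenced as stranded, ribosomal RNA depleted libraries with paired reads, per the labels, with 1 library per animal. The authors deposited 2 tables for the whole series. The first holds expected counts, the deposited estimates of reads for each RefSeq transcript, and 29.4% of its values above 0 lie within 0.01 of a whole number. The second holds a deposited signal, and it equals the first table times 1 factor per library, within a relative spread of 1.6e-05 for values of at least 50 counts, the TMM scaling that its name gives. The submitters' processing notes name bcl2fastq, HISAT2 and Partek without versions. The genome build is not named in the sources used here, and no reference genome was used.

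Expected counts of 89424 transcripts were summed to 35366 gene names, of which 30039 had a count, and rounded to whole numbers. Names of 25 genes, on 141 transcript lines, had been turned into dates by a spreadsheet and were restored, and 24 lines without a gene name were left out of the tests. Those lines held 0.364% to 2.93% of the counts. Depth per library was 10579214 to 23948159 counts over named genes. Intervals and tests cover the spread between animals, and 1 library per animal gives no separate measure of technical noise.

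The age of each animal is the only factor that the labels vary. The main test fitted age in years as a linear term to all 35 libraries with edgeR 4.0.16 (TMM, the default filterByExpr filter, a robust quasi-likelihood fit and F test) in R 4.3.3, with Benjamini-Hochberg adjustment at 0.05. Slopes are log2 changes per 10 years. A second fit used 3 age bands, split at 12 and 17 years, and tested old against young, middle against young, old against middle, and the curvature, old minus 2 times middle plus young. Bands, tests, gene lists and the rule for named genes were fixed before the data were examined. CPM values in the text use TMM-scaled library sizes unless the library total is named.

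Gene lists, 55 in all with 1574 entries, came from textbook knowledge of heart biology and cell types. Of these entries 1475 matched by gene symbol and 59 by the product name of a locus without a symbol, and 40 had no match. The match by product was made after product names and some overall means had been seen and before any fit of age. Lists with at least 5 tested members, 53 of them, were tested on the age slope by camera (limma 3.58.1) with a preset correlation of 0.01, with an estimated correlation, and by fry, each adjusted over the lists, and the estimated correlation was also used with sheet run as a term and within sheet run 2. Each list's mean log2 CPM (prior count 2) was correlated with age by Pearson's r and Spearman's rho with 100000 two-sided permutations, whose smallest p is 1e-05. The same was done for the first 5 principal components of the 2000 most variable genes and for 4 library measures.

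Named genes were those past an adjusted p of 0.05 with a mean of at least 1 CPM, a rho of the same sign and a proper symbol, up to 12 per direction by size of slope. Of the genes falling on the age slope, 1 is not reported here. In band contrasts with calls the 4 largest in each direction were taken by the same criteria, and for curvature the 4 with the smallest adjusted p. In each list described up to 4 members with the smallest p were named. NPPA, NPPB, MYH6, MYH7, COL1A1, COL3A1, CDKN1A, CDKN2A, ESR1 and ALB were always named where tested. LOC101004388, FAM228B and the immune genes of the first principal component were named after their values were seen.

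Sheet numbers in the labels fall in 4 runs, treated as possible batches. The age slope was refitted within run 2 and with the run as a term. Alternatives were DESeq2 1.42.0 size factors and its Wald test, library totals, no filter, a filter of 1 CPM in 18 libraries, a fit without robust moderation, log2 or rank of age, covariates for total count and for cell marker lists, 5 surrogate variables from sva 3.50.0, limma-voom, limma trend on the deposited signal, other thresholds, bands by rank of age, and leaving out single libraries or small sets of them. Results were compared with 100 assignments of ages or bands to libraries. The fits were tested on simulated counts with 200 changed genes per comparison. The age slope recovered 70.1% of changes of 0.5 log2, 82.1% of 1 log2 and 100% of 2 log2, and 14 of its 182 calls were false. These counts were drawn for each gene on its own, with no variation shared between genes. In the real data recovery may be lower and false calls more frequent. Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 served for tables, permutations and figures.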

Results

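Left ventricle from 35 normal female baboons aged 7.5 to 22.1 years was profiled by RNA sequencing to ask how the ageing heart changes. For contrasts in levels the animals were placed in 3 age bands. The young band held 11 animals of 7.5 to 11.9 years, the middle band 10 animals of 12 to 15.7 years and the old band 14 animals of 17.8 to 22.1 years. The total count over named genes ran from 10579214 to 23948159 per library, with a mean of 16878992 ± 3117354 (SD, n = 35), and 14626 to 16469 genes were detected. Titin (TTN) alone took 11.9% ± 1.14 (SD, n = 35) of the counts, and the mitochondrially encoded genes took 12.3% to 30.7%. The extraction text of the labels names liver, while the tissue label says left ventricle. ALB, the main secreted protein of hepatocytes, had a median of 0.0736 and a highest value of 7.25 CPM (counts scaled to library depth, here to library totals). Each library came from a separate animal, and no pair of libraries within a band agreed within sampling noise, with a lowest chi-square per degree of freedom of 16.5.

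Across adult life 5 genes rose and 2 fell with age past the threshold. That count was matched in 6 of 100 assignments of ages to libraries, the real one included, so chance cannot be excluded for it. The rising genes were SOCS3, an inhibitor of cytokine signalling through JAK and STAT, ZFP36, a protein that directs AU-rich messenger RNAs to decay, GPRC5A, an orphan receptor induced by retinoic acid, MERTK, a receptor tyrosine kinase with which macrophages clear dying cells, and TSPYL2, a relative of nucleosome assembly proteins. Among the falling genes was SENP8, a protease that acts on the ubiquitin-like protein NEDD8. Expressed per 10 years, SOCS3 rose 3.61-fold, GPRC5A 3.2-fold, ZFP36 2.4-fold, MERTK 1.71-fold and TSPYL2 1.66-fold, while SENP8 changed 0.734-fold. The slope behind the SOCS3 value, 1.85 log2 per 10 years, was 1.144 without old replicate 11, the oldest animal (adjusted p = 0.356), and 0.471 without old replicates 1 and 11, a set chosen after the data were seen (adjusted p = 0.767).

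By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 16202 genes, the steepest slope among the genes that passed was that of SOCS3, at 1.85 ± 0.367 log2 per 10 years (SE, n = 35; adjusted p = 0.0353). Its mean was 2.85 ± 1.48 CPM in the young band (SD, n = 11), 2.8 ± 1.31 in the middle band (n = 10) and 8.76 ± 13.2 in the old band (n = 14). ZFP36 had a slope of 1.26 ± 0.244 (adjusted p = 0.0288) and went from 17.5 ± 7.62 CPM in the young to 37.5 ± 26.6 CPM in the old band. GPRC5A, at 0.533 ± 0.379 CPM in the young and 1.59 ± 1.32 CPM in the old band, had a slope of 1.68 ± 0.324 (adjusted p = 0.0288). MERTK rose from 8.08 ± 1.98 to 13.9 ± 4.29 CPM between the same bands, a slope of 0.77 ± 0.154 (adjusted p = 0.0353). The smallest adjusted p, 0.00294, belonged to TSPYL2, with a slope of 0.73 ± 0.114 and means of 13.2 ± 2.21 CPM in the young, 14.4 ± 3.19 in the middle and 20.1 ± 6.53 in the old band. SENP8 fell by 0.45 ± 0.086 log2 per 10 years (adjusted p = 0.0288), from 4.62 ± 0.492 to 3.49 ± 0.624 CPM. Spearman's rho of log2 CPM with age was 0.292 for SOCS3, between 0.546 and 0.673 for the other 4 rising genes, and −0.75 for SENP8. The files place SOCS3 at bases 70034856 to 70038156 and TSPYL2 at bases 49771996 to 49778249 of separate reference sequences, and give no build name.

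**Figure D1:**
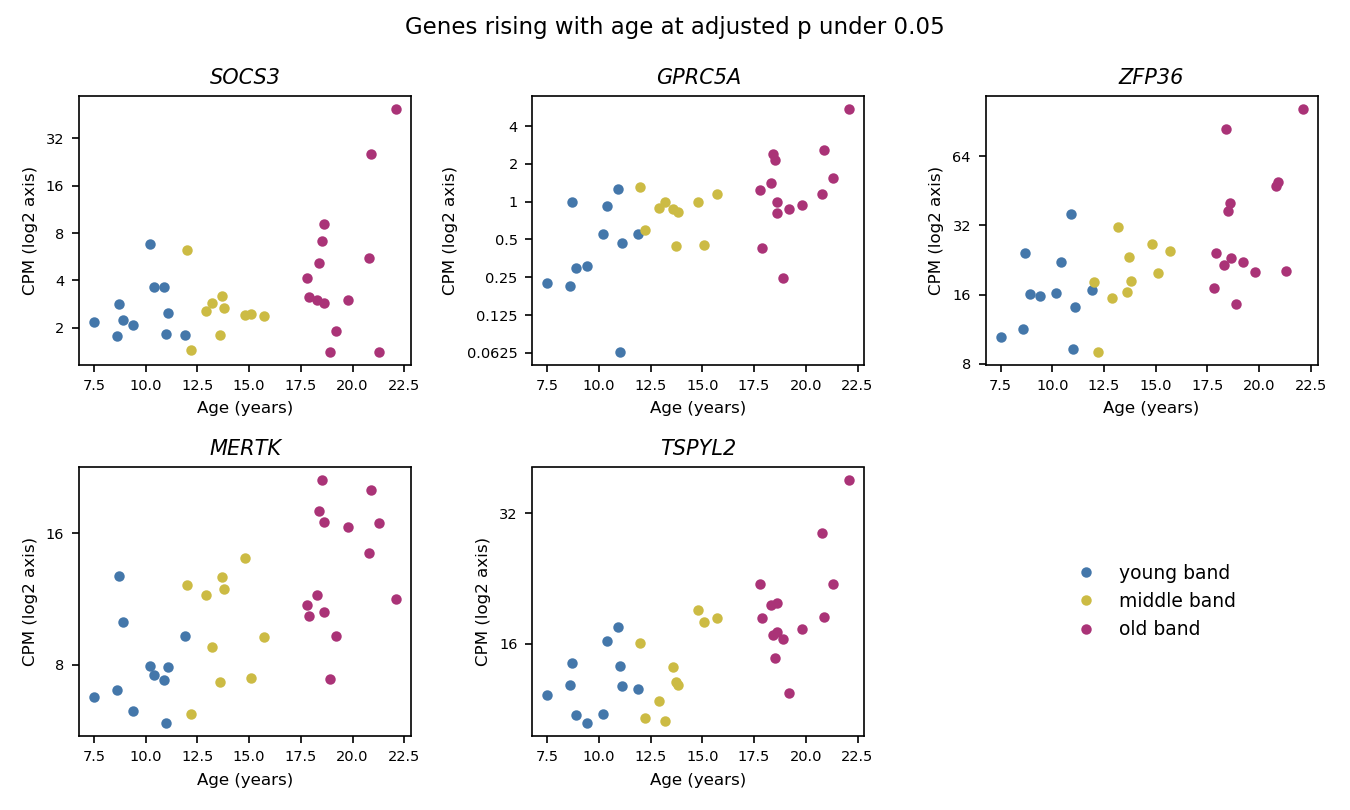
CPM (log2 axis) against age in years for the 5 genes that rose past the threshold on the age slope, 1 point per library, coloured by age band. The highest SOCS3, at 49.2 CPM, belongs to the oldest animal.

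At an unadjusted p under 0.05, 1101 genes had a rising and 992 a falling slope, 12.9% of those tested. DESeq2's Wald test gave 61 rising and 26 falling genes, limma-voom gave 1 and 2, and each kept the direction of the 7 genes. Leaving out 1 library at a time moved these counts, and TSPYL2 was past the threshold in 35 of 35 such fits. The rising count was 1 without old replicates 1 or 4 or young replicates 3, 6, 10 or 11, 2 without old replicate 11, and 3 without old replicate 6, middle replicates 6 or 10 or young replicate 1. It was 9 without old replicate 9 or young replicates 4 or 5, 10 without old replicate 13 or young replicate 2, 12 without old replicate 2 or middle replicate 8, 22 without old replicate 5 and 25 without young replicate 9. The falling count was 0 without young replicates 3 or 11, 1 without old replicates 1 or 11 or young replicates 6 or 10, 4 without old replicate 2, 5 without old replicate 13 or young replicate 9, and 6 without old replicate 5 or young replicate 4. Over the 35 fits SOCS3 passed in 24, GPRC5A and ZFP36 in 28 each, MERTK in 22 and SENP8 in 29. The libraries behind these losses are those named above with fewer calls, and for MERTK also old replicates 3 and 12 and young replicate 7, where its adjusted p was 0.0568, 0.0757 and 0.0609.

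Genes often followed in the ageing or failing heart had slopes that did not pass the same edgeR test. CDKN1A, the p21 cell cycle inhibitor, had a slope of 1.23 ± 0.317 log2 per 10 years (adjusted p = 0.11), with 6.58 ± 4.39 CPM in the young and 12.4 ± 11.8 CPM in the old band. With sheet run, the unbroken runs of numbers on the sample sheet, as a term its slope was 1.501 and passed (adjusted p = 0.0338). That call ends, as do all with that term, without old replicate 11, which had the highest CDKN1A at 48.8 CPM against 23 in the next old library. The 2 myosin heavy chains of the ventricle had slopes of 0.56 ± 0.345 for MYH6 (adjusted p = 0.494) and −0.08 ± 0.078 for MYH7, listed under LOC101010605 (adjusted p = 0.715). The fibrillar collagens COL1A1 and COL3A1 had slopes of −0.013 ± 0.246 (adjusted p = 0.991) and −0.033 ± 0.218 (adjusted p = 0.967). ESR1, the oestrogen receptor alpha, had a slope of −0.40 ± 0.168 (adjusted p = 0.301). NPPA, which encodes atrial natriuretic peptide, had a slope of −2.65 ± 1.82 (adjusted p = 0.554), but a Spearman's rho with age of 0.271. Its highest values, 101 and 22.5 CPM, were those of middle replicates 6 and 9. NPPB, CDKN2A and ALB had too few counts to be tested.

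Gene lists fixed before the data were examined were tested on the same slope. Of 53 lists with at least 5 tested members, 15 were higher and 10 lower with age by camera with a preset correlation of 0.01 and Benjamini-Hochberg adjustment. That number of lists was matched in 13 of 100 assignments of ages to libraries, the real one included. The median over the other assignments was 13 lists, so chance cannot be excluded for it, and the small camera p-values below carry this limit. Immediate early genes, collagen, matrix, complement and adipocyte lists were among the higher ones, and mitochondrial and contractile lists among the lower. With an estimated correlation none of the 53 lists passed (lowest adjusted p = 0.264), and none passed by fry, with a lowest adjusted p of 0.0617. Without old replicates 1 and 11, the libraries with the highest SOCS3 and a set chosen after the data were seen, 9 lists were higher and 10 lower, and 1 gene rose and 0 fell. The higher lists lost there were collagens and matrix (median 0.077, adjusted p = 0.118), matrix proteases and inhibitors (0.059, 0.29), NF-kappaB and cytokines (0.085, 0.227), senescence and p53 (0.019, 0.196), the unfolded protein response (0.012, 0.814), chaperones (−0.01, 0.732) and endocardial and lymphatic markers (0.357, 0.05). The lower lists lost were cardiomyocyte markers (−0.049, 0.109) and sarcomere (−0.049, 0.0565). Adrenergic and angiotensin signalling entered as higher (adjusted p = 0.046), and class II antigen presentation (0.0325) and the mitochondrially encoded genes (0.018) as lower. Lists that stayed with smaller medians included complement and coagulation (0.114 against 0.384), TGF-beta signalling (0.102 against 0.209), ketone and branched-chain amino acid catabolism (−0.056 against −0.115) and immediate early genes (0.624 against 0.932).

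The immediate early genes, transcription factors and regulators induced within minutes of a stimulus, had the highest median slope of the 53 lists. All 27 tested members had a positive slope, with a median of 0.93 log2 per 10 years (camera adjusted p = 1.08e-18; adjusted p = 0.264 with an estimated correlation). Of these, 2 rose over all genes tested and 20 adjusted over the list alone. Adjustment over the list alone, here and below, is made within each list and not over the 53 lists, so such calls are descriptive. Outside the 7 genes of the age slope, no such member passed over all genes in the main fit. Beside ZFP36 and SOCS3, the immediate early genes with the smallest p were MYC, at 1.28 ± 0.314, and ATF3, a stress-induced transcription factor, at 2.02 ± 0.539, neither past the threshold over all genes (adjusted p = 0.11 and 0.115). The mean log2 CPM of the list was 4.12 ± 0.648 in the young (SD, n = 11), 4.45 ± 0.688 in the middle and 4.79 ± 0.789 in the old band. Its Pearson r with age was 0.503 (permutation p = 0.00251, adjusted over 53 lists 0.0628) and its Spearman rho 0.468 (permutation p = 0.00521, adjusted 0.126). Without the 2 animals farthest from the median age r was 0.496. Within sheet run 2, the largest unbroken run of numbers on the sample sheet, r was 0.422 over 17 libraries (permutation p = 0.0918), and it was 0.445 within runs. The camera call with the preset correlation also held in that run alone, at adjusted p = 5.19e-06, with a smaller median of 0.541. With an estimated correlation none of the lists passed there.

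Lists of mitochondrial translation and energy metabolism were lower with age by camera with the preset correlation, and did not pass with an estimated one. In the mitochondrial ribosome list 68 of 73 tested members had a negative slope, with a median of −0.13 log2 per 10 years (camera adjusted p = 1.9e-14; adjusted p = 0.265 with an estimated correlation). The members MRPS18C, MRPL44 and MRPL32 fell by 0.24, 0.23 and 0.22, adjusted over the list alone, and 0 members passed over all genes. Complex I of the respiratory chain had 36 of 37 members with a negative slope and a median of −0.13 (camera adjusted p = 2.8e-09; adjusted p = 0.36 with an estimated correlation). Complexes II to V had 35 of 36 and a median of −0.14 (camera adjusted p = 9.1e-09; adjusted p = 0.36 with an estimated correlation). The tricarboxylic acid cycle and pyruvate dehydrogenase had 24 of 25 and a median of −0.14 (camera adjusted p = 4.68e-08; adjusted p = 0.338 with an estimated correlation). In these 3 lists 0 members passed, over all genes or adjusted over the list alone. With the cardiomyocyte list as a covariate the medians of complex I and of complexes II to V were −0.021 and −0.022, and neither list passed (adjusted p = 0.163 for both). That of the tricarboxylic acid cycle list shrank to −0.041 and still passed with the preset correlation (0.037). An estimated correlation was not used with this covariate. Ketone and branched-chain amino acid catabolism had 19 of 21 members with a negative slope (camera adjusted p = 9.62e-05; adjusted p = 0.265 with an estimated correlation). PPM1K, a phosphatase that activates branched-chain ketoacid breakdown, had its smallest p, at −0.40 ± 0.144. The 13 mitochondrially encoded genes had a median of −0.24 and did not pass (camera adjusted p = 0.0586). The mitochondrial ribosome score had r = −0.407 with age (permutation p = 0.0158, adjusted over 53 lists 0.0838) and rho = −0.289 (permutation p = 0.0932, adjusted 0.225), with r = −0.395 without the 2 farthest ages, −0.423 within sheet run 2 (permutation p = 0.0902) and −0.541 within runs. Cardiomyocyte markers moved the same way, with a median of −0.13 (camera adjusted p = 0.00029; adjusted p = 0.338 with an estimated correlation).

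**Figure D2:**
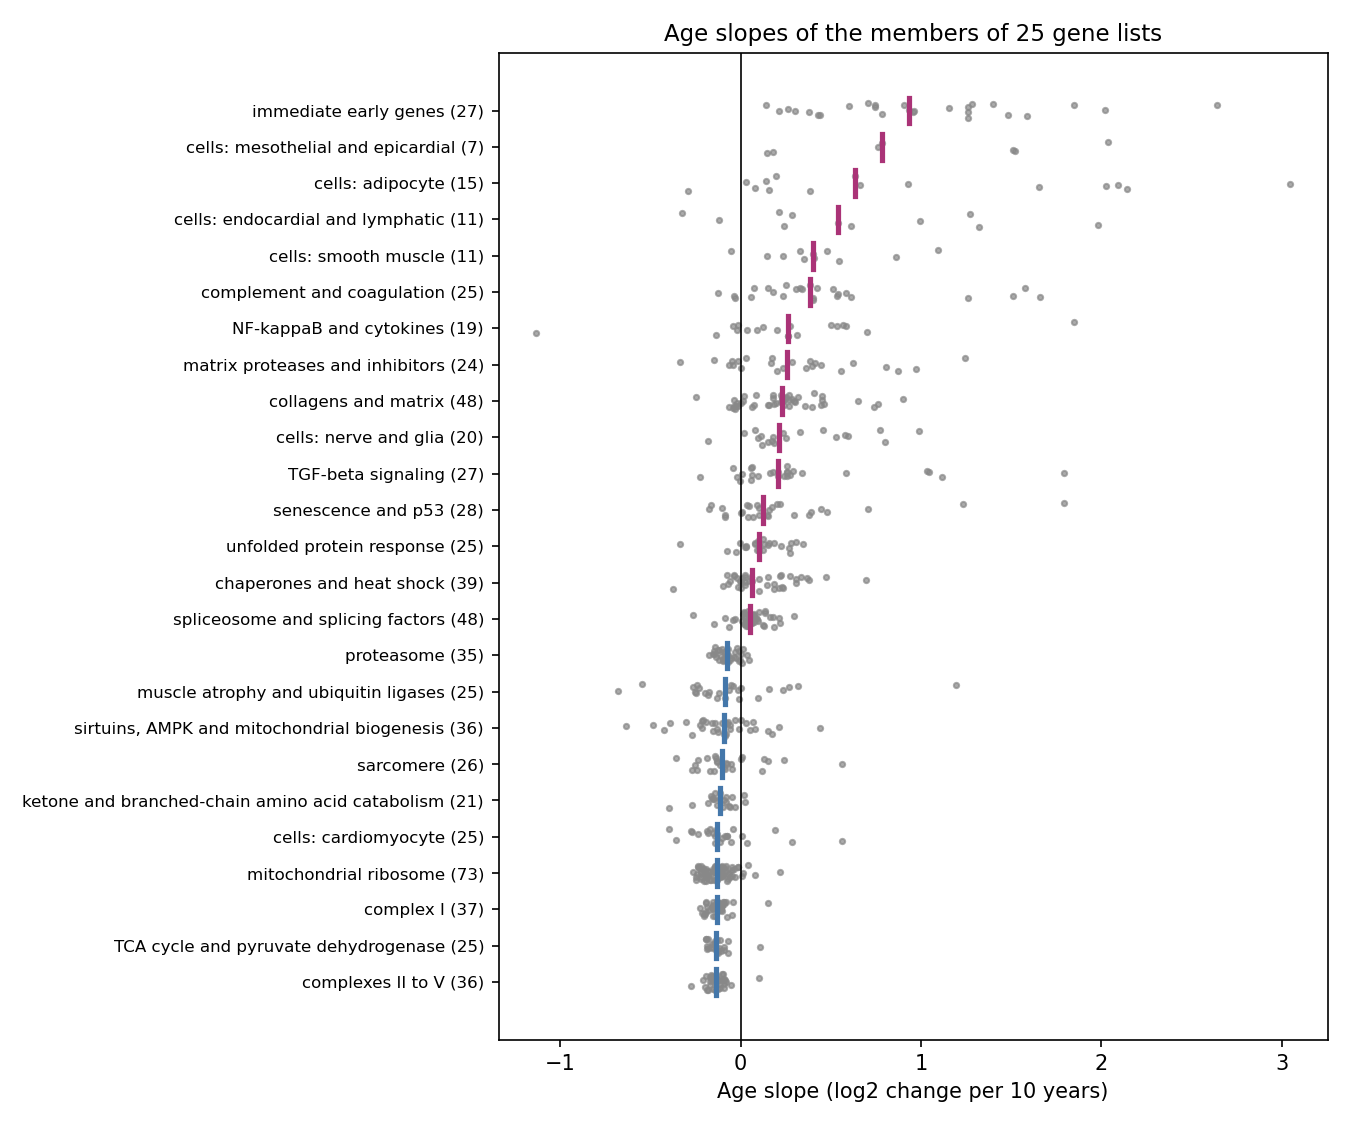
Age slope in log2 change per 10 years for each tested member (grey points) of the 25 lists past the threshold by camera with a preset correlation, with the number of tested members in brackets and the list median as a coloured bar. Medians run from −0.14 for complexes II to V to 0.93 for the immediate early genes.

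Contractile and energy-sensing lists of the heart muscle cell were also lower by camera with the preset correlation. The sarcomere list had 19 of 26 members with a negative slope (median −0.11, camera adjusted p = 0.000353; adjusted p = 0.338 with an estimated correlation). Adjusted over the list alone, 2 of its members fell, the ventricular light chain MYL2 by 0.36 and the titin cap protein TCAP by 0.25 log2 per 10 years, and 0 passed over all genes. MYL2 went from 10300 ± 1580 CPM in the young to 7830 ± 1610 CPM in the old band. In the list of sirtuins, AMP kinase and mitochondrial biogenesis, 27 of 36 members had a negative slope (camera adjusted p = 0.000344; adjusted p = 0.264 with an estimated correlation). The r of its score with age lay between −0.618 and −0.454 with 1 library left out. No list score passed by permutation over the 53 lists (lowest adjusted p = 0.0628 by r). There PRKAB2, a subunit of AMP kinase, fell by 0.39, the orphan receptor ESRRB fell by 0.64 and the coactivator PPRC1 rose by 0.44, adjusted over the list alone. Muscle atrophy and ubiquitin ligase genes were lower (18 of 25 negative, camera adjusted p = 0.00402; adjusted p = 0.264 with an estimated correlation). FBXO32, the muscle ubiquitin ligase atrogin-1, fell by 0.55 from 421 ± 88 CPM to 297 ± 78.8 CPM and KLHL38 fell by 0.68, adjusted over the list alone. The proteasome had 30 of 35 negative slopes and a median of −0.08 (camera adjusted p = 5.48e-05; adjusted p = 0.362 with an estimated correlation), with 0 members past the threshold in either count.

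Matrix, complement and stress lists were higher with age by the same test. Collagens and matrix had 39 of 48 members with a positive slope and a median of 0.23 (camera adjusted p = 2.76e-05; adjusted p = 0.369 with an estimated correlation), with 0 members past the threshold in either count. Its smallest p was that of THBS1, a matricellular glycoprotein, at 0.90 ± 0.3. Matrix proteases and inhibitors had 18 of 24 positive slopes (median 0.26, camera adjusted p = 0.000473; adjusted p = 0.265 with an estimated correlation). Adjusted over the list alone 8 of them rose and 1 fell, among them ADAMTS9 (0.97), ADAMTS4 (1.24), TIMP2 (0.36) and MMP14 (0.40), and 0 passed over all genes. In TGF-beta signalling 23 of 27 slopes were positive (camera adjusted p = 9.62e-05; adjusted p = 0.264 with an estimated correlation). CTGF, a matrix-linked growth factor, rose by 1.12 and the repressor SKI by 0.21, adjusted over the list alone, and neither passed over all genes. Complement and coagulation had 22 of 25 positive slopes and a median of 0.38 (camera adjusted p = 6.42e-07; adjusted p = 0.264 with an estimated correlation). The complement genes C3 (1.51), CFD (1.26) and CFB (1.58) and the plasminogen activator PLAT (0.51) rose adjusted over the list alone, and 0 passed over all genes. NF-kappaB and cytokine genes had 14 of 19 positive slopes (camera adjusted p = 0.000371; adjusted p = 0.338 with an estimated correlation), with SOCS3 and the interleukin 1 receptor IL1R1 (0.70) rising adjusted over the list alone. In the senescence and p53 list 23 of 28 slopes were positive (median 0.12, camera adjusted p = 0.0011; adjusted p = 0.264 with an estimated correlation). Adjusted over the list alone 5 members rose and over all genes 0, with slopes of 1.23 for CDKN1A, 0.17 for the p53 regulator MDM2, 0.48 for the cell cycle inhibitor CDKN2B and 0.71 for GADD45B.

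Splicing and protein-folding lists had smaller medians. Spliceosome and splicing factors had 42 of 48 positive slopes with a median of 0.05 (camera adjusted p = 0.000473; adjusted p = 0.369 with an estimated correlation), and RBM20, a splicing factor for titin, had a slope of −0.26 ± 0.104. The unfolded protein response had 21 of 25 positive slopes (camera adjusted p = 0.00236; adjusted p = 0.375 with an estimated correlation) and chaperones 29 of 39 (camera adjusted p = 0.00912; adjusted p = 0.518 with an estimated correlation). In these 3 lists 0 members passed in either count. Without old replicate 11, the oldest animal, the last 2 lists no longer passed, at adjusted p = 0.106 and 0.394, nor did the chaperones with sheet run as a term (0.275) or the spliceosome list within sheet run 2 (0.0646).

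Marker lists of several cell types passed by camera with the preset correlation, and 0 with an estimated one. Adipocyte markers had 14 of 15 positive slopes and a median of 0.64 (camera adjusted p = 0.000473; adjusted p = 0.36 with an estimated correlation). Of these, 6 rose adjusted over the list alone, among them FASN, the fatty acid synthase (2.15), PLIN1, a lipid droplet coat protein (2.09), and PPARG, the adipocyte transcription factor (0.66). Mesothelial and epicardial markers had 7 of 7 positive slopes and a median of 0.78 (camera adjusted p = 0.000564; adjusted p = 0.264 with an estimated correlation), with PRG4, the secreted lubricant proteoglycan (2.04), C3, KRT18 (1.52) and WT1 (0.78) rising adjusted over the list alone. PRG4 had 7.39 ± 5.21 CPM in the young and 27.8 ± 55.5 CPM in the old band. Old replicate 11 had 218.7 CPM, the next old library 34.3, and the median of the other old libraries was 9.81. Nerve and glia markers had 19 of 20 positive slopes (camera adjusted p = 0.000737; adjusted p = 0.338 with an estimated correlation), with the myelin gene MBP (0.80) and the neurotrophin receptor NGFR (0.77) rising adjusted over the list alone. Smooth muscle markers had 10 of 11 (camera adjusted p = 0.012; adjusted p = 0.36 with an estimated correlation) and endocardial and lymphatic markers 9 of 11 (camera adjusted p = 0.028; adjusted p = 0.338 with an estimated correlation). Cardiomyocyte markers had 20 of 25 negative slopes (median −0.13, camera adjusted p = 0.00029; adjusted p = 0.338 with an estimated correlation), with CKMT2, the mitochondrial creatine kinase of striated muscle, falling by 0.39 and MYL2 by 0.36 adjusted over the list alone. In these cell lists 0 members passed over all genes. Without old replicate 11 the nerve and glia list no longer passed (adjusted p = 0.0661), nor did the endocardial and lymphatic list (0.126), which was also lost with library totals (0.104) and without young replicates 2 (0.06) or 3 (0.0551) or old replicate 14 (0.0516). With sheet run as a term the smooth muscle and the endocardial lists did not pass (0.0656 and 0.058), nor within sheet run 2 alone (0.595 and 0.217), where the smooth muscle median was 0.069 against 0.403 over all libraries.

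As scores per library, 0 of 15 cell lists followed age past an adjusted p of 0.05. The highest correlation was that of the mesothelial and epicardial score, with r = 0.441 (permutation p = 0.0071, adjusted over 15 lists 0.106) and rho = 0.351 (permutation p = 0.0393, adjusted 0.147). Without the 2 farthest ages r was 0.352. Within sheet run 2 it was 0.626 over 17 libraries (permutation p = 0.00134, adjusted 0.0201), and within runs 0.467. In run 1 it was −0.166 over 8 libraries and in run 4 it was 0.781 over 6. Old replicate 14, at 17.8 years, was the oldest animal of run 4, and the next oldest was 12.2 years. That library had the highest mesothelial and adipocyte scores of the run (3.151 and 6.641). The run 4 correlations of both scores therefore lean on 1 library, which the values within runs also include. The adipocyte score had r = 0.315 (permutation p = 0.0635, adjusted 0.176) and rho = 0.397 (permutation p = 0.0188, adjusted 0.145), with r = 0.194 without the 2 farthest ages, 0.432 within sheet run 2 (permutation p = 0.0744), −0.191 in run 1, 0.898 in run 4 and 0.458 within runs. Its highest values were 6.641 in old replicate 14, 6.523 in old replicate 11, 5.938 in young replicate 5 and 5.844 in old replicate 6. Without old replicate 11 r was 0.2. The cardiomyocyte score had r = −0.309 (permutation p = 0.0705, adjusted 0.176) and rho = −0.231 (permutation p = 0.182, adjusted 0.303), with r = −0.218 without the 2 farthest ages, −0.389 within sheet run 2 (permutation p = 0.122) and −0.478 within runs. At an unadjusted permutation p under 0.05 by r were the mesothelial score and the endocardial and lymphatic score (r = 0.397, permutation p = 0.0184, adjusted 0.138; rho = 0.378, permutation p = 0.0268, adjusted 0.145; r = 0.328 without the 2 farthest ages, 0.358 within sheet run 2 and 0.418 within runs). By rho the adipocyte score and the atrial and conduction score were under 0.05 as well, the latter with rho = 0.371 (permutation p = 0.0291, adjusted 0.145) and r = 0.278 (permutation p = 0.107, adjusted 0.201), r = 0.306 without the 2 farthest ages, 0.093 within sheet run 2 (permutation p = 0.723) and 0.138 within runs.

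**Figure D3:**
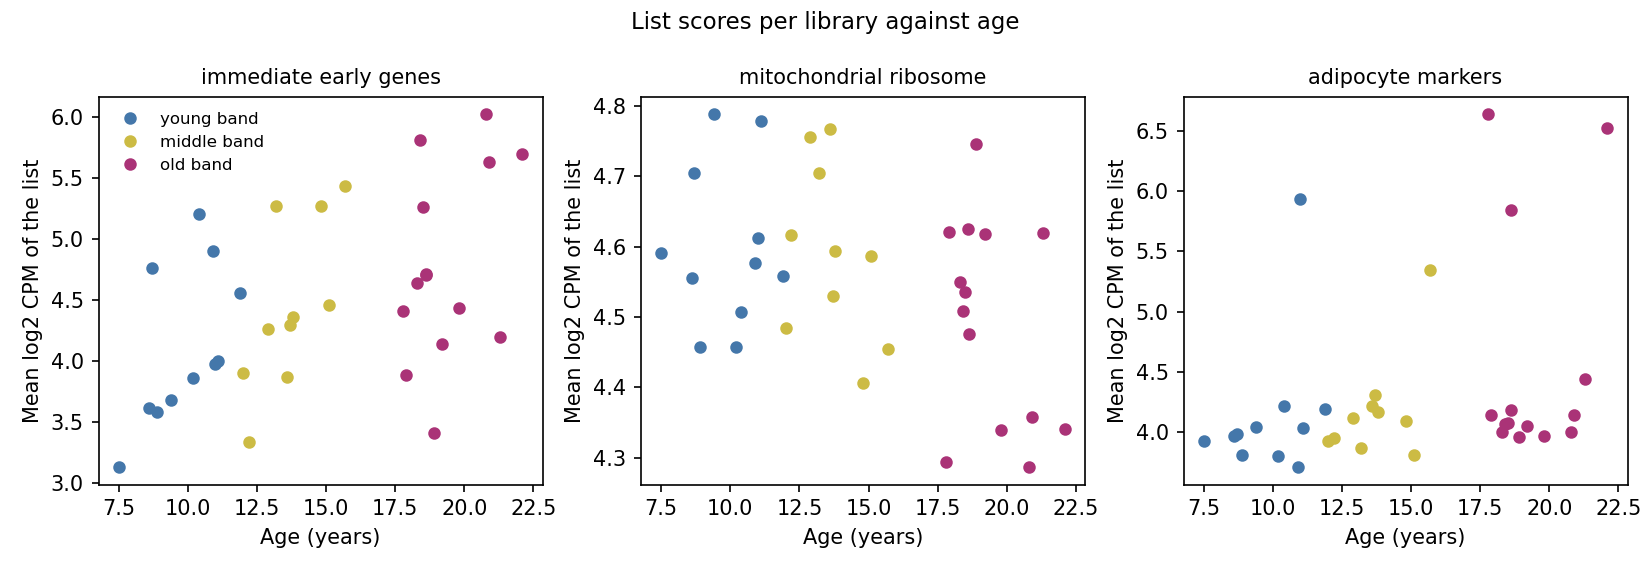
Mean log2 CPM of the immediate early, mitochondrial ribosome and adipocyte lists in each library against age in years, coloured by age band. The correlation with age is r = 0.503 for the first, −0.407 for the second, with its lowest values in the old band, and 0.315 for the third, whose high values sit in a few libraries.

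The other 28 lists did not pass in the main fit. Among immune lists the median slope was −0.03 for macrophage and monocyte markers (camera adjusted p = 0.545), 0.04 for the interferon response (0.379) and −0.06 for class II antigen presentation (0.263). T and NK markers had a median of 0.17 (0.0586). Young replicate 2, of sheet run 4, had the highest T and NK score, 3.164 in mean log2 CPM. The r of that score with age was 0.149 over all libraries. It was 0.27 without young replicate 2 and 0.082 without old replicate 11. The outcome also differed with sheet run. With it as a term the T and NK list was higher with a median of 1.112 (adjusted p = 8.01e-06) and the interferon response with 0.30 (0.011), and within sheet run 2 alone their medians were 1.553 (9.23e-13) and 0.352 (0.00317), all by camera with the preset correlation. With an estimated correlation the adjusted p was 0.361 and 0.62 with the term and 0.436 and 0.652 within run 2. In either fit 0 of the lists passed. Over all libraries but old replicates 1 and 11, without the run term, the T and NK median was −0.281 (adjusted p = 0.842). The cytosolic ribosomal proteins had a median of −0.002 over 73 members (0.933), and autophagy and lysosome genes 0.006 over 41 (0.974). Fatty acid oxidation had a median of −0.04 but a mean of 0.07 (0.505), and was lower with sheet run as a term (−0.14, adjusted p = 0.0027; 0.415 with an estimated correlation). It was higher with the cardiomyocyte list as a covariate (0.05, 0.0185). In the hypoxia list (0.0586) 3 members rose adjusted over the list alone, PFKFB3, a regulator of glycolysis (0.86), ANGPTL4, an inhibitor of lipoprotein lipase (1.46), and ANKRD37 (0.51). With sheet run as a term the fibroblast (0.000801) and hypoxia (0.0394) lists were also higher, and the mitochondrially encoded genes (0.00231) and calcium handling (0.0233) lower. Within sheet run 2 alone the cell cycle list was higher (median 0.16, adjusted p = 0.0035; 0.0574 with the run term). With an estimated correlation none of these passed. Adjusted p with the run term was then 0.356 for fibroblast, 0.254 for hypoxia, 0.361 for mitochondrially encoded, 0.312 for calcium handling and 0.395 for cell cycle genes. The fibroblast median was 0.015 without old replicates 1 and 11 (adjusted p = 0.842). With the cardiomyocyte list as a covariate the sarcomere (0.336) and proteasome (0.0736) lists no longer passed. Neither did collagens and matrix (0.114), matrix proteases and inhibitors (0.0736), NF-kappaB and cytokines (0.0743), adipocyte (0.0684), smooth muscle (0.0727) and endocardial and lymphatic markers (0.226). The sarcomere list shares MYL2 with that covariate, so its loss comes in part by construction. With the immediate early list as a covariate, a fit chosen after the data were seen, the calls of collagens and matrix (median 0.076, adjusted p = 0.341), matrix proteases and inhibitors (0.152, 0.114), TGF-beta signalling (0.08, 0.192), NF-kappaB and cytokines (0.008, 0.547), spliceosome (0.018, 0.341), the unfolded protein response (0.056, 0.0688), and mesothelial (0.655, 0.155), smooth muscle (0.092, 0.642), endocardial (0.241, 0.259) and cardiomyocyte markers (−0.084, 0.0702) ended. The immediate early list shares SOCS3 with the NF-kappaB and cytokine list, so that loss too comes in part by construction. The hepatocyte and skeletal muscle lists had 4 testable members each and were not tested.

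Between age bands the mean of the middle band stood apart in 3 genes, and few genes passed in single steps. FAM198B, which encodes a Golgi protein, was highest in middle age, at 120.5 ± 20.2 CPM in the young (SD, n = 11), 158.1 ± 26.5 in the middle (n = 10) and 107.6 ± 18.4 in the old band (n = 14). Old animals were lower than middle ones in FAM198B by 0.55 ± 0.098 log2 and in LOC101004388, an LDHB pseudogene, with a difference of −3.78 ± 0.655, both at adjusted p = 0.0177 by edgeR's quasi-likelihood test over 16063 genes. The pseudogene can share reads with LDHB, and its middle mean of 7.54 ± 14.3 CPM came from middle replicates 6 and 10, at 35 and 34.3 CPM against a median of 0.791.

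The test of whether the step from young to middle differs from that from middle to old found 3 genes, all with their highest mean in the middle band, though the median of NPPA was highest in the old band. They were LOC101004388 (−7.22 ± 1.07 log2, adjusted p = 0.0013), NPPA (−8.74 ± 1.55, adjusted p = 0.0184) and FAM198B (−0.95 ± 0.175, adjusted p = 0.0254). NPPA reached 101 CPM in middle replicate 6 and 22.5 in middle replicate 9, against band medians of 0.25 in the young, 0.272 in the middle and 0.318 in the old. Leaving out 1 library ended the old against middle call of FAM198B for middle replicates 4, 6 or 8 (adjusted p = 0.0799, 0.131 and 0.0743) and of LOC101004388 for middle replicates 6 or 10 (0.132 and 0.111). It ended the curvature call of FAM198B for middle replicates 2, 3, 4, 6, 8 or 9 (0.0587, 0.077, 0.149, 0.167, 0.133 and 0.0604) and of NPPA for middle replicates 6 or 9 (1 and 0.0525). With sheet run as a term 0 genes passed in either contrast.

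Old against young and middle against young gave 0 genes in either direction by edgeR. At an unadjusted p under 0.05 were 1416 genes (8.82% of those tested) and 717 genes (4.46%). The second share is no more than a threshold of 0.05 passes without any effect. DESeq2's Wald test gave 11 higher and 5 lower genes for old against young and 0 for middle against young. The smallest adjusted p for old against young was 0.125, the value of MERTK (0.79 ± 0.159 log2) and FAM228B (0.54 ± 0.11). On simulated counts with the same design the old against young test recovered 65.7% of changes of 0.5 log2 and 100% of changes of 2 log2. The simulated genes share no variation between libraries, so recovery in the real data may be lower. The absence of calls therefore does not show that such changes are absent.

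Sheet numbers in the labels fall in 4 runs that differ in age, though the labels do not call them batches. Run 2 held 17 animals of 8.7 to 22.1 years, run 1 held 8 of 13.2 to 20.8 years, run 3 held 4 of 17.9 to 18.9 years and run 4 held 6 of 7.5 to 17.8 years. Within run 2 alone edgeR called 0 genes of 15988, with 1130 rising and 545 falling at an unadjusted p under 0.05. The 7 genes kept their direction there, with slopes of 2.55 for SOCS3, 1.73 for GPRC5A, 1.173 for ZFP36, 0.62 for MERTK, 0.69 for TSPYL2 and −0.49 for SENP8 among them, at adjusted p from 0.249 to 0.39. With sheet run as a term over all 35 libraries, 101 genes rose and 17 fell, and 7 of the 7 genes stayed past the threshold. Of the list members named above, MYC, CDKN1A, C3, CFD, IL1R1, ADAMTS9, FASN, PPARG, PRG4, NGFR, MBP and PFKFB3 rose and MRPS18C fell past the threshold over all genes with the run term, and not without it. The count of called genes with the run term fell to 0 without old replicate 11 and to 3 without old replicate 14, and it rose to 400 rising and 240 falling without old replicate 2 and 414 and 168 without old replicate 13. The rising count was also over 1.5 times higher without young replicates 2 (229), 4 (203) or 9 (168), and the falling count was 41, 73 and 27 there, 33 without middle replicate 8 and 29 without young replicate 7. Falling counts of 7 to 11 followed without old replicates 1 (8), 6 (10) or 7 (11), middle replicates 4 (7), 5 (11), 6 (11) or 7 (10), or young replicates 1 (11) or 6 (8).

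None of the first 5 principal components of the 2000 most variable genes followed age past an adjusted p of 0.05. The first, with 16.8% of the variance, had large positive loadings for the immune genes JCHAIN, CXCL9 and IL7R, and r = 0.302 with age (permutation p = 0.0786, adjusted over 5 components 0.144) and rho = 0.333 (permutation p = 0.0518, adjusted 0.0937), with r = 0.23 without the 2 farthest ages, 0.519 within sheet run 2 (permutation p = 0.0334) and 0.427 within runs. The third had the highest r with age, 0.369 (permutation p = 0.0276, adjusted 0.138), with rho = 0.325 (permutation p = 0.0562, adjusted 0.0937), r = 0.291 without the 2 farthest ages, 0.458 within sheet run 2 (permutation p = 0.0642), −0.283 in run 1, 0.785 in run 4 and 0.373 within runs. The run 4 value leans on old replicate 14, the oldest animal of that run, which had the highest score on this component. Total count, share of the 10 highest genes, genes detected and mitochondrial share did not follow age either. The closest was genes detected, with r = 0.301 (permutation p = 0.0793, adjusted over 4 measures 0.307) and rho = 0.326 (permutation p = 0.0564, adjusted 0.226), r = 0.368 without the 2 farthest ages, 0.247 within sheet run 2 (permutation p = 0.334) and 0.234 within runs.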

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

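The test of whether 1 or 2 libraries decide the NPPA mean, and the fit without middle replicates 6 and 9, were chosen only after the result was seen. A sample far from the others in a band of 10 was looked for in 33 groups of values, and chance marks about 1 in 20 such groups.

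NPPA, the gene of atrial natriuretic peptide, stood out in the middle band, where the highest library had 101 CPM and the next 22.5. The change of its step between bands, young to middle against middle to old, was −8.74 log2 (adjusted p = 0.0184). Without middle replicates 6 and 9 this value was −2.59 with an adjusted p of 1, so the call rests on these libraries. Atrial tissue in the piece is a candidate explanation. There the genes MYL7, MYL4, SLN and KCNA5 had a mean rank of 10.8 ± 3.49 among 35 libraries (SE over ranks pooled from both libraries). The pooled ranks come from 2 animals, so this SE does not measure a spread between animals. In middle replicate 6 the ranks were 9, 2, 9 and 7, and in middle replicate 9 they were 34, 4, 10 and 11. The ranks are too broad to decide. A biological response of single hearts stays open and was not tested, since the labels give no other trait of these animals.

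LOC101004388, an LDHB pseudogene, had a difference between its steps of −7.22 log2 (adjusted p = 0.0013), and FAM198B one of −0.95 (adjusted p = 0.0254). In the middle band the highest SOCS3 was 6.24 CPM against a next of 3.19. The highest adipocyte score there was 5.35 against 4.31, the highest erythroid and blood score 6.03 against 4.61, and the highest mesothelial and epicardial score 3.06 against 2.53, each in mean log2 CPM. The highest mitochondrial share in the middle band was 27.3% against 20.4%. Transcripts without a gene name, used in no comparison, took up to 2.93% of the counts, in middle replicate 1, and 0.364% in the lowest library.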

How the results depend on the processing

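The fits with the immediate early list as a covariate, without old replicates 1 and 11, without middle replicates 6 and 9, the permutation test of list scores, the estimated correlation with sheet run, and the left-out libraries for lists and bands were chosen only after the data were seen. The age slope called 5 rising and 2 falling genes, and DESeq2 size factors and a fit without robust moderation gave the same counts. Rising and falling genes were 15 and 1 with library totals, where the median slope of all genes was 0.057, 27 and 8 with no filter, 61 and 26 by DESeq2's Wald test, 101 and 17 with sheet run as a term, and 15 and 4 at an adjusted p of 0.1. They were 1 and 0 with log2 of age, at an adjusted p of 0.01, without the 4 letter-labelled animals and without old replicates 1 and 11, and 1 and 1 with rank of age. Limma-voom and limma trend on the deposited signal each gave 1 rising gene and the same 2 falling. They were 0 and 0 in sheet run 2 alone, with the cardiomyocyte list, 4 cell lists or the immediate early list as covariates, with surrogate variables, and without the youngest 2 and oldest 2 animals. The cause was not tested, except that smaller sets hold fewer animals and other thresholds pass other numbers by construction. SOCS3 and ZFP36 are members of the immediate early list, so their loss with that covariate also comes in part by construction.

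With 1 library left out, rising genes numbered 1 (without old replicates 1 or 4 or young replicates 3, 6, 10 or 11) to 25 (without young replicate 9; 22 without old replicate 5; 12 without old replicate 2 or middle replicate 8; 10 without old replicate 13 or young replicate 2; 9 without old replicate 9 or young replicates 4 or 5). They were 2 without old replicate 11 and 3 without old replicate 6, middle replicates 6 or 10 or young replicate 1. Falling genes numbered 0 (without young replicates 3 or 11) to 6 (without old replicate 5 or young replicate 4), with 5 without old replicate 13 or young replicate 9, 4 without old replicate 2, and 1 without old replicates 1 or 11 or young replicates 6 or 10. Old against middle gave 0 (without middle replicate 6) to 2 lower genes, with 1 without middle replicates 4, 8 or 10. Curvature gave 1 (without middle replicates 6 or 9) to 3. Old against young, middle against young and the higher side of the other contrasts gave 0 in each such fit. Higher lists numbered 12 to 18 and lower lists 10 to 12.

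Old against young gave 11 higher and 5 lower genes by DESeq2's Wald test. Old against middle gave 1 lower gene with the filter of 1 CPM in 18 libraries and by the Wald test, and 0 with sheet run, with bands by rank and without middle replicates 6 and 9. Curvature gave 0 with that filter, with sheet run and with bands by rank, and 1 without middle replicates 6 and 9. The filter drops LOC101004388 and NPPA by construction, while FAM198B stays in and no longer passed. Higher and lower lists were 0 and 0 with an estimated correlation (over all libraries, with sheet run as a term and within sheet run 2), by fry and by permutation of the list score. With the immediate early list as a covariate 6 lists were higher, without old replicates 1 and 11 there were 9, and with the cardiomyocyte list as a covariate 6 were lower. Fatty acid oxidation, with no call in the main fit, was higher with that covariate (adjusted p = 0.0185) and lower with sheet run as a term (adjusted p = 0.0027). Within sheet run 2, 1 cell score followed age. The cause was not tested. On simulated counts the curvature test recovered 20.9% of changes of 0.5 log2, 41.8% of 1 log2 and 95.5% of 2 log2, so most bends of 0.5 log2 would be missed at this depth and number of animals.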

Other observations

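The tests of sheet run and of dilution by other cells, the assignments for list medians, and the fits with sheet run less 1 library were chosen only after the result was seen; the genes named in the first paragraph were too. With sheet run as a term, 118 genes passed edgeR's quasi-likelihood test and all 118 kept their sign without the term. Among 101 rising genes the slope was 2.64 ± 0.504 log2 per 10 years for FASN, the fatty acid synthase (adjusted p = 0.0136), 2.24 ± 0.451 for the lubricant proteoglycan PRG4 (0.0229), 1.79 ± 0.346 for the Wnt antagonist SFRP1 (0.0136) and 1.79 ± 0.343 for the hyaluronan-binding protein TNFAIP6 (0.0136). It was 1.91 ± 0.464 for C3 (0.0422), 2.58 ± 0.625 for the interleukin 33 receptor IL1RL1 (0.0421) and 1.64 ± 0.334 for MYC (0.0245). Among 17 falling genes were COQ10A, a coenzyme Q binding protein (−0.47 ± 0.116, 0.0448), the mitochondrial import protein TIMM13 (−0.32 ± 0.079, 0.0428) and MRPS18C (−0.30 ± 0.071, 0.0407). The assignment of ages within runs gave as many calls in 1 of 100 cases, the real one, with 118 against a highest other of 5. The run term gave the highest count of the settings tried over all libraries, a choice these assignments do not correct for. Chance is therefore not firmly excluded for this count. The count was 0 without old replicate 11, which had 49.2 CPM of SOCS3 and 219 CPM of PRG4, and 3 rising without old replicate 14. It was 400 rising and 240 falling without old replicate 2 and 414 and 168 without old replicate 13.

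At an adjusted p under 0.1, 15 genes rose and 4 fell without the run term, a threshold other than the main one. Among those past 0.05 but under 0.1 were LMNA, which encodes nuclear lamins A and C (0.40 ± 0.087, adjusted p = 0.0631), EDA2R, a receptor of the tumour necrosis factor family and p53 target (1.04 ± 0.226, 0.0631), PGF, a placental growth factor of the VEGF family (1.04 ± 0.225, 0.0631), and FADS1, a fatty acid desaturase (0.59 ± 0.129, 0.0631). EDA2R went from 2.57 CPM in the young to 5.28 CPM in the old band and LMNA from 64.4 to 81.1 CPM.

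Immediate early genes had a median slope of 0.932, and 1 of 100 assignments of ages gave a median as far from 0, the real one, with a highest other of 0.782. With ages assigned within sheet runs the highest other, 1.0823, lay above the real 0.8505. The list was singled out among 53 after the result, a choice these assignments do not correct for, and its score had an adjusted p of 0.0628 by r and 0.126 by rho over the 53 lists, so chance stays open for it. Sheet run as the cause would have taken most of the slope away, and 0.85 remained with the run as a term and 0.541 within sheet run 2 alone. Library measures as the cause would have left no relation, and the partial correlation with age given 4 measures was 0.511 (permutation p = 0.00196). Without the 3 libraries of highest score, old replicates 9, 3 and 11, rho was 0.356 (permutation p = 0.0447), too close to its bound to decide whether a few libraries carry it. Tissue handling at collection may still contribute and cannot be told apart from age, since the residual correlation with the chaperone score was 0.132 (permutation p = 0.451) and the labels give no collection times; a biological effect of age stays open.

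The mitochondrial ribosome list had a median slope of −0.13, and 2 of 100 assignments gave one as far from 0, with sizes of 0.133 for the real ages and 0.152 for the highest other. With ages assigned within sheet runs the real size, 0.2007, lay above the highest other, 0.1568. This list too was singled out after the result, and its score had an adjusted p of 0.0838 by r and 0.225 by rho over the 53 lists, so chance stays open for it. Normalization as the whole cause would have turned the sign, and the median was −0.072 with library totals and −0.13 with DESeq2 size factors. The slope was thus smaller with library totals, where the median slope of all genes was 0.057. Part of its size may depend on the scaling. A lower share of cardiomyocytes may account for part of it, since the median was −0.059 with the cardiomyocyte list as a covariate (camera adjusted p = 0.000313), which is neither 0 nor most of the slope. For complex I and complexes II to V the medians shrank from −0.133 and −0.137 to −0.021 and −0.022 with that covariate and the calls ended (camera adjusted p = 0.163 for both). Dilution by all other cells alike cannot be told apart, as the adipocyte score changed by 0.497 more per 10 years than the macrophage score with a permutation p of 0.174. A change within heart muscle cells with age stays open as a hypothesis.

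Assignments of ages or bands to libraries tested the other counts. The 7 genes on the age slope were matched in 6 of 100 assignments, with a highest other of 156, so chance cannot be excluded for that count. The 2093 genes at an unadjusted p under 0.05 were matched in 4 of 100, with a highest other of 2734, a share so close to the bound of 0.05 that chance is not firmly excluded there. The 25 lists by camera were matched in 13 of 100, with a highest other of 31 and a median of 13 lists over assignments, so chance cannot be excluded for that number of lists. The 2 genes of old against middle were matched in 5 of 100 (highest other 1247) and the 3 of curvature in 5 of 100 (highest other 756), and chance cannot be excluded for either. Old against young, middle against young and the slope within sheet run 2 gave 0 genes, which 100 of 100 assignments match by construction, so these counts test nothing; the highest others were 4, 41 and 3. Assignments that called many more genes than the real one, such as 1247, point to a structure of the libraries, whose source was not tested.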
